A study of Mus musculus with 6 samples.

How the data were processed

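RNA sequencing was used on leukemia stem cells taken from mice 13 days after leukemia cells had been transplanted, with 3 libraries from bone marrow and 3 from liver. Per the labels' protocols, RNA was extracted with a column kit and turned into libraries with a low-input full-length cDNA kit followed by tagmentation, a chemistry that does not mark the strand. Per the submitters' processing notes, the tools were bcl2fastq 2.19.0, Trimmomatic 0.36, STAR 2.6.0c, DESeq2 1.16.1 and R 3.4.1. The genome build, the annotation and the read counter are not given in the sources used here.

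The deposited table holds a signal per gene and library, which are read counts that the authors divided by 1 size factor per library with DESeq2, per the name of the deposited table and the submitters' processing notes. In each library 100% of the values were whole multiples of its smallest value within a tolerance of 0.01, so whole reads could be recovered. The recovered totals were 15.4, 16.2 and 18.5 M reads for bone marrow replicates 1, 2 and 3, and 13.8, 9.73 and 11.4 M for liver replicates 1, 2 and 3. The liver libraries were therefore shallower, and 1 read was worth 0.744 to 0.898 normalized counts in bone marrow and 0.988 to 1.42 in liver. The labels call the 3 libraries of a tissue technical replicates and do not name separate animals, so p-values measure only the spread between these libraries, which may be technical in part. Replicates 1 and 2 of a tissue differ in sex-linked transcripts and are therefore not repeat libraries of 1 sample, while it is open whether replicate 3 is independent of them. No library pair of a group agreed within sampling noise: the chi-square per degree of freedom was between 6.75 and 27.8. All 6 libraries were kept as separate samples.

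From the deposited values, log2(normalized count + 1) was fitted with limma 3.58.1 in R 4.3.3, with tissue as the only term, a variance trend, two-sided tests and Benjamini-Hochberg adjustment. Fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 10 normalized counts over the 6 libraries were tested, 14298 of the 53735 in the table. An adjusted p under 0.05 counted as a difference. Gene lists were tested with camera at a preset correlation of 0.01, where at least 5 members were measured. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. The 40 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule names Lipg, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 50 normalized counts in the higher tissue and no overlap between tissues, and up to 4 members with the smallest adjusted p of each list described. Gene models without a name were passed over, 2 among the higher and 4 among the lower genes. Any other gene was chosen after its values were seen.

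Alternatives planned beforehand were TMM factors, quantile normalization, pseudocounts of 0.5 and 10, no filter, a mean of at least 50, robust variance moderation, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a term, a minimum log2 change of 1, and leaving out each library in turn. Thinning to equal depth, leaving out both replicate 3 libraries and a surrogate variable from sva 3.50.0 were added after seeing the data. On data simulated from these libraries for liver against bone marrow (14079 genes tested), the fit recovered 23.4% of genes changed 1.5-fold, 50% at 2-fold, 86% at 4-fold and 93.3% at 8-fold, with 8 false calls among 129 and 0 of the wrong sign. In the same simulation 1 of 1 shifted gene lists and 0 of 36 unshifted lists were called. The simulation drew genes and libraries independently, and its lists were random genes. It therefore cannot show how often camera calls lists of correlated genes by error. It also held no difference shared by replicate number, so its count of false calls need not hold for these libraries. The estimated correlation was 0.39 for G2/M and mitosis and 0.86 for primary granule genes. Gene positions are those of GENCODE M21 on GRCm38, matched by symbol for 11689 of the 14298 tested genes (81.75%), and that annotation was not used for counting here. Intervals and floors of 3 reads cover counting error only, since reads copied by PCR are not independent molecules. Figures were drawn with matplotlib 3.10.9.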

Results

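Transcript levels were measured in 6 libraries of mouse leukemia stem cells, the cell fraction of a leukemia that can regrow the disease, 3 from bone marrow and 3 from liver. Depth ran from 15.4 to 18.5 M reads in bone marrow and from 9.73 to 13.8 M in liver. The most abundant transcript, Rn18s-rs5, took 1.66% to 1.83% of a library, and mitochondrially encoded genes took 0.887% to 1.03%. Tissue was not the main axis of variation. The first principal component, with 40.9% of the variance, set replicate 1 of each tissue apart from replicate 2, and the second, with 27.9%, set the tissues apart.

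**Figure D1:**
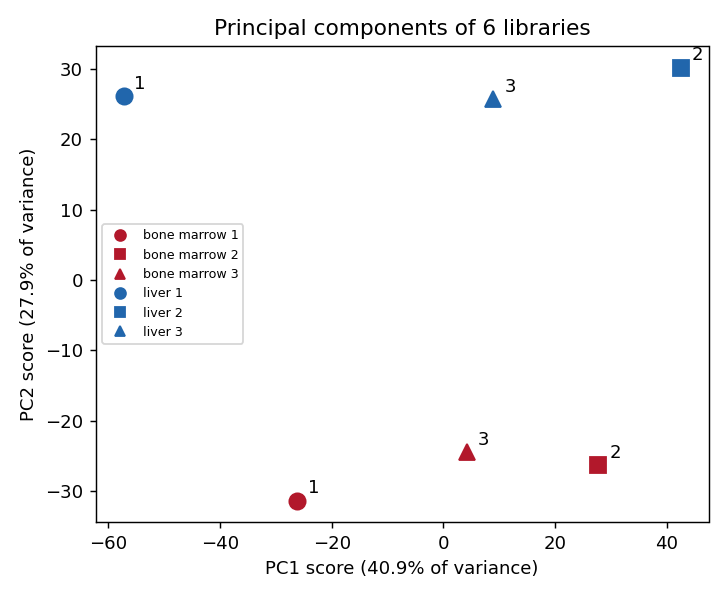
Scores of the 6 libraries on the first and second principal components of the log2 values, with the share of variance on each axis, color for tissue and marker for replicate number. The tissues separate on the second component (27.9%), and replicate 3 of each tissue lies between replicates 1 and 2 on the first (40.9%).

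Replicates 1 and 2 differed in sex-linked transcripts in both tissues, although the labels give every library as male. Xist, the RNA that silences an X chromosome in female cells, stood at 4860 normalized counts in bone marrow replicate 1 and 6229 in liver replicate 1, against 4.28 and 1.42 in replicate 2. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y summed to 145 and 0 in replicate 1 and to 2987 and 2675 in replicate 2. Bone marrow replicate 1 thus held 4.87% of the Y-linked level of bone marrow replicate 2 (162 reads), while liver replicate 1 held 0 reads. The source of this difference, and its part in genes lower in liver, was not tested. Replicate 3 held both, with 2486 (bone marrow) and 2425 (liver) for Xist and 1553 and 1634 for the Y-linked sum. These genes were chosen after their values were seen.

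**Figure D2:**
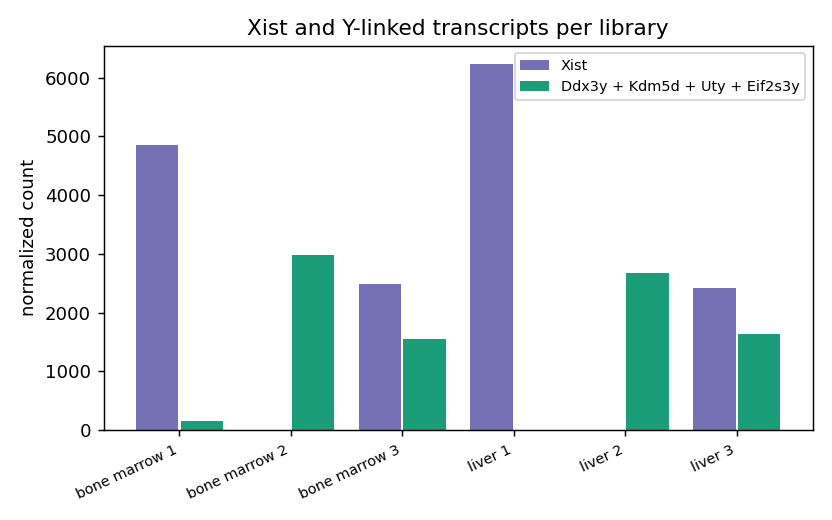
Normalized counts of Xist and of the summed Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y in each library, as bars starting at 0. Replicate 1 is dominated by Xist (4860 and 6229), replicate 2 by the Y-linked genes (2987 and 2675), and replicate 3 holds both.

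The comparison of liver with bone marrow asks which transcripts leukemia stem cells carry at different levels in the liver, and the series names LIPG in its title. Lipg, which encodes endothelial lipase, a secreted phospholipase acting on lipoproteins, was higher in liver. Its level was 42.7 ± 12 normalized counts in liver against 2.79 ± 2.79 in bone marrow (SD, n = 3 each), a log2 fold change of 3.73 ± 0.60 (SE). The limma adjusted p was 0.042. With the replicate number as a term it was 0.015, and with that term and without both replicate 3 libraries 0.23. The 3 liver libraries held 31.6, 55.4 and 40.9 normalized counts and the 3 bone marrow libraries 0.898, 5.99 and 1.49, so that every liver library lay above every bone marrow library. These values rest on 105 reads in liver and 10 in bone marrow. The gene of this symbol lies on chromosome 18 from 74939322 to 74961263 on the minus strand (GRCm38), and no other annotated gene shares its exon bases. The call was lost in 5 of the 6 fits that left out 1 library, with an adjusted p of up to 0.230, and after thinning to equal depth (adjusted p = 0.058), while the log2 fold change stayed between 3.35 and 4.29 in those fits.

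Of 14298 genes tested, 145 differed between the tissues, 60 higher and 85 lower in liver, and 64 of them changed by at least 1 log2 unit, 23 up and 41 down. At an unadjusted p under 0.05 there were 2244 genes. The tissues did not overlap in 3192 genes, 22.3% of those tested. Chance gives 10% for 6 independent libraries. It is open whether replicate 3 is independent of replicates 1 and 2, so no excess over chance can be read from this share. The count of differing genes depended on single libraries, with 6 genes without bone marrow replicate 3, 8 without liver replicate 3, 11 and 17 without bone marrow replicates 1 and 2, 86 without liver replicate 2 and 427 without liver replicate 1. Without both replicate 3 libraries it was 2, with the replicate number as a term 525 and with both of these changes 15. DESeq2 on the recovered reads gave 638 genes, array weights 3217 and a surrogate variable 1513. Of the 45 passing genes named by the rule besides Lipg, 5, 7 and 3 kept their call without bone marrow replicates 1, 2 and 3, and 45, 24 and 4 without liver replicates 1, 2 and 3. Their log2 fold changes stayed between 0.825 and 1.22 times those with all libraries.

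The 12 named genes that rose in liver included those of 2 granule peroxidases, a serine protease, 2 chemokines, a chemokine receptor and 2 heat shock proteins. Epx, eosinophil peroxidase, had 0 reads in bone marrow and 135 in liver, at least 64.1-fold higher at a floor of 3 reads over the bone marrow group (adjusted p = 0.027). Mpo, myeloperoxidase, rose from 58.7 ± 0.36 to 1287 ± 984 normalized counts (log2 fold change 3.99, adjusted p = 0.047), with 283, 2250 and 1328 in the 3 liver libraries. Its bone marrow level rests on 213 reads over the group, where counting error exceeds so small an SD. Prss34, a serine protease of basophils and mast cells, rose from 207 ± 24.9 to 2546 ± 1236 (3.48, adjusted p = 0.016). The neutrophil chemokine receptor gene Cxcr2 rose from 9.08 to 77.3 (2.93, adjusted p = 0.018), the chemokine gene Ccl6 from 340 to 2036 (2.57, adjusted p = 0.0017) and Cxcl2, which encodes a ligand of Cxcr2, from 151 to 551 (1.88, adjusted p = 0.010). Hspa1a and Hspa1b, near-identical copies of the inducible HSP70 gene, rose by 2.43 and 2.09 on the log2 scale. Crispld2 (3.12), Akr1c18, a steroid dehydrogenase gene (2.65), the protease inhibitor gene Slpi (1.99) and the histone gene Hist1h2bm (1.98) complete the 12. Values of Hspa1a, Hspa1b and Hist1h2bm are uncertain because similar copies can share reads, and Mpo, Hspa1a and Slpi share exon bases with Gm11505, Gm20481 and Mir7678. Of the 12, Ccl6 kept its call in each fit that left out 1 library, and of these fits Epx, Mpo, Crispld2, Slpi and Hist1h2bm kept theirs only in the 1 without liver replicate 1. Without bone marrow replicates 1, 2 and 3 the calls of 2, 3 and 1 of the 12 were kept, and without liver replicates 1, 2 and 3 those of 12, 7 and 1.

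The genes that fell most in liver included a mast cell tryptase gene and genes of inflammatory chemokines and secreted proteins. Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, fell from 10109 ± 301 to 1249 ± 76.0 normalized counts (log2 fold change -3.02 ± 0.061 (SE), adjusted p = 1.7e-06). Tpsb2, a mast cell tryptase gene, had 439 reads in bone marrow and 1 in liver, a ratio of 308 with a 95% counting interval of 55.0 to 12201 (adjusted p = 0.0091). Crisp1 fell from 7622 to 1846 (-2.04, adjusted p = 7.6e-04) and Crisp3 from 434 to 161 (-1.43), both genes of cysteine-rich secretory proteins. The chemokine genes Ccl7 (-2.56), Ccl2 (-1.75) and Ccl5 (-1.51) fell, as did Il1rl1, which encodes the receptor of interleukin-33 (-1.47). Erv3 (-5.09), Csn2, the gene of the milk protein beta-casein (-4.36), Fam178b (-2.04) and the ephrin receptor gene Epha3 (-2.04) complete the 12. Fam178b shares exon bases with D430040D24Rik. Tph1 and Crisp1 kept their call in each fit that left out 1 library. Of the 12, 3, 3 and 2 kept it without bone marrow replicates 1, 2 and 3, and 12, 10 and 3 without liver replicates 1, 2 and 3.

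**Figure D3:**
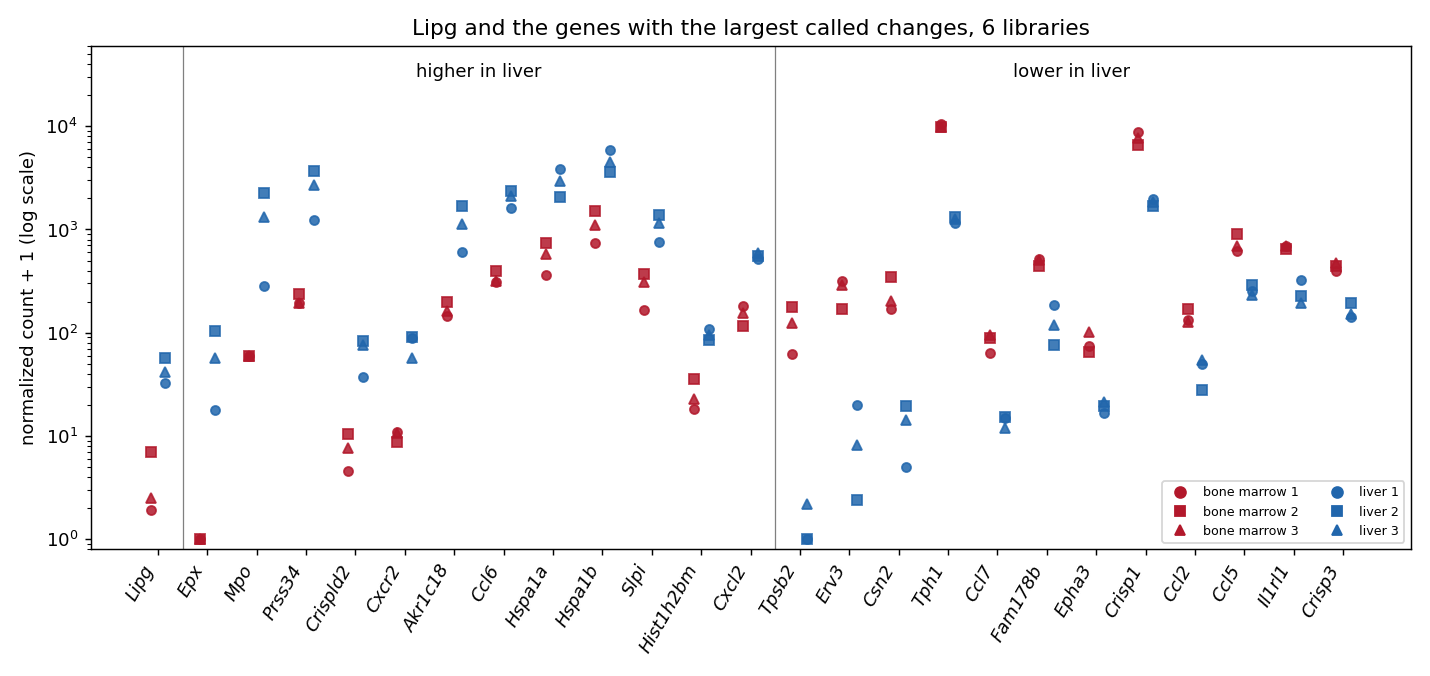
Normalized counts plus 1 on a log axis for Lipg, the 12 genes with the largest rise and the 12 with the largest fall in liver, with color for tissue and marker for replicate number. Each point is 1 library, and the tissues do not overlap in any of these genes. Tph1 separates from 10109 to 1249 with little spread, and Mpo ranges from 283 to 2250 among the liver libraries.

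Of 37 gene lists tested, 18 were called by camera at its preset correlation, 9 higher and 9 lower in liver. With an estimated correlation the count was 0 and the lowest adjusted p 0.27, with 2 lists at an unadjusted p under 0.05, and fry called 6, of which 4 were among the 18. These 4 were DNA replication and G1/S (fry adjusted p = 0.016), cytosolic ribosomal proteins (0.041), immediate early and dissociation genes (0.041) and oxidative phosphorylation (0.047). Cell cycle genes were higher in liver. All 30 measured genes of DNA replication and G1/S had a positive fold change (median 0.29), 4 rose over all genes tested, 26 did not pass, and 21 passed adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). The 4 were Uhrf1, a hemimethylated-DNA binding factor (1621 to 2279), the replication factors Cdc45 (599 to 875) and Cdt1 (630 to 881), and the helicase subunit gene Mcm5 (3880 to 5149). All 28 genes of G2/M and mitosis had a positive fold change (median 0.28), of which Hmmr rose, 27 did not pass and 20 passed adjusted over the list alone (adjusted p = 0.33 with an estimated correlation).

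Energy metabolism and biosynthesis lists were shifted by less. The 33 oxidative phosphorylation genes had positive fold changes with a median of 0.14, among them Cox6b1 (0.29) and Cox5a (0.29). None passed over all genes and 6 did adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). For glycolysis the median over 21 genes was 0.11, 0 passed and 3 passed adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). For MYC targets and ribosome biogenesis it was 0.11 over 30 genes, Hspe1 rose, 29 did not pass and 7 passed adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). Fatty acid synthesis and desaturation had a median of 0.14 over 18 genes, of which 0 passed either way (adjusted p = 0.33 with an estimated correlation), Fads3 having a log2 fold change of 1.45. Without liver replicate 2 the calls of glycolysis (median 0.07, adjusted p = 0.062) and of fatty acid synthesis and desaturation (0.04, adjusted p = 0.19) were lost, the latter also without bone marrow replicate 1 (0.12) or 3 (0.10), and without liver replicate 1 the median of MYC targets and ribosome biogenesis was 0.05.

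The list of immediate early and dissociation genes, which respond to stress and to cell isolation, was higher with a median of 0.27. Of its 25 genes 5 rose (Hspa1a, Hspa1b, Dnajb1, Atf3 and Hsp90aa1), 20 did not pass, and adjusted over the list alone 7 were higher and 2 lower (adjusted p = 0.33 with an estimated correlation). Primary granule and promyelocyte genes had a median of 0.60 over 14 genes, with Mpo the 1 that rose, 13 not passing and 5 passing adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). Elane, neutrophil elastase, stood at 33.6, 631 and 350 normalized counts in liver and 14.4, 35.1 and 17.8 in bone marrow. Mature neutrophil genes had a median of 1.60 over 9 genes, with Cxcr2 the 1 that rose, 8 not passing and 2 passing adjusted over the list alone (adjusted p = 0.62 with an estimated correlation). The medians of primary granule and mature neutrophil genes were 0.10 and 0.37 without liver replicate 2, with both calls lost (adjusted p = 0.37 each), and 1.18 and 2.62 without liver replicate 1. Both calls were also lost without bone marrow replicate 1 (0.40 and 1.23) and without liver replicate 3 (0.43 and 1.05). Mpo, Elane and Lcn2 were highest in liver replicates 2 and 3, the libraries with Y-linked reads, while Cxcr2 stood at 86.9, 89.5 and 55.4 normalized counts in liver replicates 1, 2 and 3.

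As a list, basophil and mast cell genes were lower in liver (median -0.64 over 13 genes), with 11 negative and 2 positive fold changes. Tpsb2, Il1rl1 and the chemokine gene Ccl3 fell, Prss34 rose, and 9 did not pass. The protease gene Mcpt8 stood at 925 normalized counts in bone marrow and 1714 in liver without passing, so the fall was not shared by all genes of these cells. Adjusted over the list alone 8 were lower and 1 higher (adjusted p = 0.33 with an estimated correlation). Interferon response genes had a median of -0.32 over 27 genes, with Gbp2 (1328 to 827) and the RNA sensor gene Ddx58 (770 to 535) falling and 25 not passing. Adjusted over the list alone 5 were lower and 1 higher (adjusted p = 0.33 with an estimated correlation). Erythroid genes had a median of -0.37 over 13 genes, of which Car2 fell, 12 did not pass and 5 passed adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.09 over 30 genes, of which 0 passed over all genes and 9 were lower adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). The median of interferon response genes was -0.20 without bone marrow replicate 2 and that of erythroid genes -0.60 without liver replicate 1, with both lists still called.

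The other 5 lower lists held 1 gene that passed over all genes. TGF-beta response genes had a median of -0.24 over 14 genes, with Id2 falling from 1035 to 507, and 4 were lower and 1 higher adjusted over the list alone (adjusted p = 0.62 with an estimated correlation). MAPK feedback targets had a median of -0.31 over 17 genes with 0 passing, and 2 lower and 1 higher adjusted over the list alone (adjusted p = 0.34 with an estimated correlation). No gene passed over all genes or adjusted over the list alone among cholesterol synthesis (median -0.08, adjusted p = 0.42 with an estimated correlation), mitochondrially encoded genes (-0.15, adjusted p = 0.51 with an estimated correlation) and dendritic cell and MHC class II genes (-0.61, adjusted p = 0.65 with an estimated correlation). Each of these 5 calls was lost without 1 of several libraries. The TGF-beta response median was -0.20, -0.19 and -0.16 without bone marrow replicate 2, bone marrow replicate 3 and liver replicate 1, where the call was lost, and -0.42 without liver replicate 2. Without the same 3 libraries the calls of MAPK feedback targets (-0.32, -0.32 and -0.29) and of dendritic cell and MHC class II genes (-0.39, -0.51 and -0.32) were lost, the latter having -0.94 without liver replicate 3. The call of cholesterol synthesis was lost without bone marrow replicate 1 (-0.06) and without liver replicates 1, 2 and 3 (-0.14, -0.09 and -0.12), and that of mitochondrially encoded genes without bone marrow replicate 1 (-0.13) and liver replicate 2 (-0.10).

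**Figure D4:**
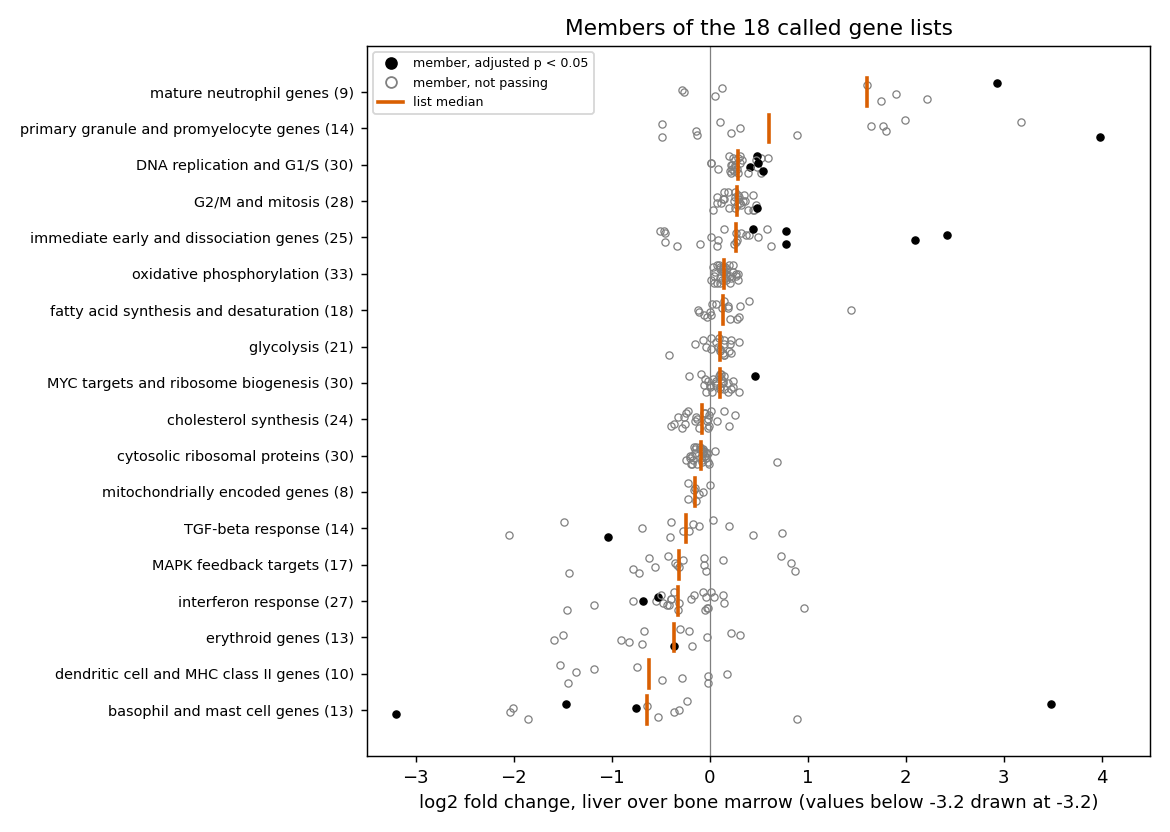
Log2 fold change of liver over bone marrow for the measured members of the 18 called lists, with filled points for members past the threshold, open points for the rest and a bar at each list's median. Values below -3.2 are drawn at -3.2. All 30 members of DNA replication and G1/S lie above 0, and basophil and mast cell genes have a median of -0.64 with Prss34 at 3.48.

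Camera did not call the lists of lipid uptake and lipases, PUFA metabolism, fatty acid oxidation or survival genes, while fry called PUFA metabolism and survival genes. Of 16 lipid uptake and lipase genes Lipg was the 1 that rose, and the median was -0.14 while the mean was 0.05. Among 18 genes of PUFA and eicosanoid metabolism Ptges3, a prostaglandin E synthase gene, rose by 0.32 on the log2 scale, with a camera adjusted p of 0.082 and a fry adjusted p of 0.041. Adjusted over the list alone 2 were higher and 1 lower. Fatty acid oxidation had 0 of 23 genes passing (median -0.04). Among 12 survival genes of the BCL2 and IAP families Birc3 fell from 584 to 386 (median -0.10, camera adjusted p = 0.21, fry adjusted p = 0.038). NF-kB and TNF response genes moved both ways, with Cxcl2 and Tnf rising, Ccl2, Ccl3, Ccl5 and Birc3 falling and 21 of 27 not passing (camera adjusted p = 0.11). Adjusted over the list alone 7 were higher and 11 lower. The list of stem and progenitor genes had 1 of 24 passing, the endoglin gene Eng, which fell from 422 to 269 (camera adjusted p = 0.41). In the lists of the unfolded protein and ATF4 response, NRF2 and iron handling, adhesion and homing, monocytes and megakaryocytes, Atf4, Atf3, Gsr and Cxcr2 rose and Cx3cr1 and Itga2b fell, with no list called. The medians of the unfolded protein and ATF4 response (0.06) and of megakaryocyte and platelet genes (-0.41) depended on single libraries, with 0.13 and -0.79 without liver replicate 1, where camera called both (adjusted p = 0.0082 and 0.00029), and the other sign without liver replicate 2 (-0.01 and 0.19). With an estimated correlation and all libraries their adjusted p were 0.65 and 0.80. No gene passed in the lists of hypoxia, p53 targets, pro-apoptotic BCL2 genes, JAK-STAT targets, T and NK cells and drug efflux, and none was called. Median and mean had opposite signs for monocyte genes (-0.19 and 0.16) and pro-apoptotic genes (-0.06 and 0.02), as they did for lipid uptake, and camera gave the sign of the median for monocyte and lipid uptake genes and that of the mean for pro-apoptotic genes.

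Several transcripts of liver and immune cells were not detected. Alb, Ttr, Fgb and Serpina1a of hepatocytes, Clec4f and Vsig4 of Kupffer cells, Cd3e of T cells and Ly6g of neutrophils had 0 reads in every library, which allows up to 3 reads each per library. Other immune cell transcripts were detected. Over all libraries the neutrophil genes S100a8, Ngp and Ltf had 161, 187 and 158 reads and the B cell gene Ighm 83. Of the mature neutrophil list 9 of 18 genes were measured, and of the T and NK cell list 8 of 22. The hepatocyte list (7 of 33 genes measured) and the list of liver sinusoidal endothelial genes (10 of 20) were not called, with camera adjusted p of 0.31 and 0.76. Other members of the liver cell lists were abundant in both tissues. Apoa1 stood at 4194 normalized counts in bone marrow and 2680 in liver, Apoe at 874 and 512, Ass1 at 251 and 383, and Ecm1 of the stellate list at 10786 and 6805, and none of these passed. Kupffer cell, hepatic stellate and B cell lists had under 5 measured members and were not tested. Gata2, a transcription factor of progenitors, mast cells and basophils, stood at 14025 ± 596 normalized counts in bone marrow and 12022 ± 1590 in liver. These single markers were chosen outside the rule for named genes.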

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

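Thinning to equal depth, leaving out both replicate 3 libraries and the surrogate variable were chosen after seeing the data. TMM factors, quantile normalization, pseudocounts of 0.5 and 10, no filter, a mean of at least 50, robust moderation and edgeR on the recovered reads gave 122 to 159 genes, and edgeR's 135 were all among the 145. None of the 145 genes changed sign under any alternative, but they were selected on these same libraries, so a change of sign was unlikely from the start. Of the 45 passing genes named by the rule besides Lipg, Tph1 alone kept its call in every alternative (21 of 21). The fewest were 11, for Epx (11 of 20) and Eng (11 of 21), while Crispld2 kept its call in 12 of 20 and Mpo in 13 of 21. DESeq2 on the recovered reads gave 638 genes (281 higher, 357 lower), and the cause was not tested. Array weights, whose fit did not converge and put most weight on both replicate 3 libraries (2.17 and 6.32 against 0.317 to 0.746), gave 3217 (1566 and 1651). A surrogate variable gave 1513 (688 and 825), and a minimum log2 change of 1 gave 64 (23 and 41) by its construction. Leaving out each library in turn gave 6 to 427 genes (1 to 207 higher, 5 to 220 lower) and 12 to 16 lists, with the lowest gene count without bone marrow replicate 3 and the highest without liver replicate 1. Without both replicate 3 libraries limma called 2 genes (0 higher, 2 lower; 802 at an unadjusted p under 0.05). Lipg had a log2 fold change of 3.36 thinned to equal depth (adjusted p = 0.058), 3.56 without both replicate 3 libraries (0.87) and 3.35 to 4.29 leaving out each library (0.037 to 0.230). It passed in 12 of 20 alternatives, over which its adjusted p ran from 3.1e-05 to 0.87, and a mean of at least 50 removed it. Of the 37 gene lists, 0 were called with an estimated correlation and 6 by fry, 4 of these among the 18 that camera called. Lipg was low in bone marrow, where it rests on 10 reads although these libraries were the deeper ones.

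The replicate numbers share no stated animal or batch. Deviations from the group means correlated across genes at 0.44, 0.40 and 0.06 for replicates 1, 2 and 3, and liver replicate 3 correlated more with bone marrow replicate 2 (0.15) than with its own number, so the rule that every pair exceed 0.1 was not met and the design stayed unpaired. This is no evidence against pairing, since replicate 3 lies near its group means, and Xist and the Y-linked genes follow the number in both tissues. With the number as a block 525 genes were called (202 higher, 323 lower) and Lipg had 3.73 (adjusted p = 0.015), against 15 genes (4 and 11) with the block and without both replicate 3 libraries, where Lipg had 3.56 (adjusted p = 0.23).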

Other observations

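The scan of gene families and the tests of replicate 3, of Mpo, Epx and Prss34, of the heat shock genes and of other splits were chosen after the values had been seen.

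Genes were grouped by the stem of their symbol into 196 stems of at least 8 tested genes, of which camera called 33 at its preset correlation. Histone genes stood out most at that setting, though not with an estimated correlation. Similar histone copies can share reads, so they are not separate measurements. Of 55 genes with the stem Hist, 53 had a positive fold change in liver with a median of 0.78, and 4 rose (adjusted p = 0.42 with an estimated correlation). The 48 genes of the large mitochondrial ribosomal subunit (Mrpl) had a median of 0.15 and the 29 of the small one (Mrps) 0.17, while the 59 Rpl genes of the cytosolic ribosome had -0.11 (each adjusted p = 0.40 with an estimated correlation). All 14 proteasome genes with the stem Psmd were positive, with a median of 0.11 (adjusted p = 0.40 with an estimated correlation). CC chemokine genes (Ccl) had a median of -0.75 over 11 genes, with 4 falling and Ccl6 rising (adjusted p = 0.42 with an estimated correlation), and all 10 carbonic anhydrase genes (Car) were negative, with a median of -0.46, of which 1 fell (adjusted p = 0.40 with an estimated correlation).

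In both tissues replicate 3 lay between replicates 1 and 2. Its Xist level was 51.2% of replicate 1 in bone marrow and 38.9% in liver, and its Y-linked level 52.0% and 61.1% of replicate 2, sums of 103% and 100.02%, which argues against cells of 1 sex. Other genes far apart in replicates 1 and 2 put its share of replicate 1 at a median of 47.8% (41 genes) and 43.1% (135 genes), so replicate 3 may hold both kinds of cells. A broader test did not decide. Replicate 3 was the middle value in 43.7% of genes in bone marrow and 50.8% in liver, where chance gives 33.3%. Replicates 1 and 2 were the middle value in 27.9% and 28.4% in bone marrow and 22.6% and 26.5% in liver. The residual of replicate 3 from the best mixture was 7.16 (bone marrow) and 4.03 (liver) times the read sampling variance. Fitted the same way, replicates 1 and 2 had 41.1 and 14.0 in bone marrow and 14.0 and 7.30 in liver. Library preparation noise is not known here, so these residuals do not decide for or against a mixture. Pooling of the samples behind replicates 1 and 2, and a separate animal carrying both leukemia populations, cannot be told apart, and if pooling occurred the 3 libraries of a tissue are not 3 independent samples.

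Mpo, Epx and Prss34 were higher in liver, with Mpo 4.78, 37.5 and 22.2 times higher in replicates 1, 2 and 3 (ratios of same-numbered libraries with 1 added to each count), while of other mast cell and basophil protease genes Tpsb2 fell, Cpa3 stood at 0.224, 0.247 and 0.279 of bone marrow (adjusted p = 0.071) and Mcpt8 at 1.82, 1.83 and 1.90 times it (adjusted p = 0.38). These adjusted p are from the unpaired limma fit, although the ratios pair libraries by number. Mpo was the 1 primary granule gene of 14 that passed, and that list's call was lost (adjusted p = 0.65 with an estimated correlation). Mature neutrophils as the source of Mpo are argued against, because S100a8 plus S100a9, their most abundant transcripts, exceeded their bone marrow mean by at most 6.93% of the excess of Mpo in any liver library. This does not cover immature granulocytes, and some neutrophils in liver replicates 2 and 3 stay open. There Lcn2 was 7.20 and 6.82 times the level of the same-numbered bone marrow library, with 1 added to each count. S100a8 was 7.63 and 6.11, Ngp 7.27 and 5.33 and Elane 17.5 and 18.6 times that level. None of these genes passed the limma test, and S100a8 and Ngp had 161 and 187 reads over all libraries. In liver replicate 1 the ratios were 2.05 for Lcn2, 0.820 for S100a8, 1.34 for Ngp and 2.25 for Elane. In liver replicate 1, 0 Y-linked reads allow male host cells a share of at most 0.111% if they carry the Y-linked level of liver replicate 2, in which Mpo would need 1.48% and Prss34 6.85% of the transcripts, so such cells are limited and not excluded. Granulocyte progenitors of the host in liver replicates 2 and 3 cannot be told apart from leukemia cells, since the Y-linked level of liver replicate 2 was 89.6% of that in bone marrow and no marker separates the 2 sources, and a response of the leukemia cells to the liver stays open and untested.

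Hspa1a, Hspa1b, Dnajb1 and Hsp90aa1 rose in liver. The 5 heat shock members of the immediate early and dissociation list had a median log2 fold change of 0.78 with 4 past the threshold, while its other 20 members had a median of 0.197 with 1 past it. Over the 11 genes with the stem Hspa the median was 0.133, with 2 past the threshold (adjusted p = 0.42 with an estimated correlation). Stress of cell isolation may differ between a liver and a bone marrow preparation, and with isolation and tissue fully confounded it cannot be told apart from a difference between the tissues. Hspa1a was 10.8, 2.83 and 5.09 times higher in liver in replicates 1, 2 and 3.

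The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 145 genes with limma, and the highest of the others 0, with up to 1626 genes at an unadjusted p under 0.05.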
